A study of Mus musculus with 6 samples.

How the data were processed

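RNA was measured in 6 cultures of primary mouse renal tubular epithelial cells, 3 from Setd2(F/F)Ksp-Cre+ mice (KO) and 3 from Setd2(F/F) littermates (WT). Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, kidneys came from mice of 4 to 5 weeks, the cortex was digested with liberase and strained, and cells were plated in medium with EGF at 20 ng/ml and hydrocortisone at 100 nM. Total RNA was purified with the RNeasy Mini Kit and made into libraries with the TruSeq RNA Sample Prep kit, per the labels' protocols. Without a step that selects tubular cells in those protocols, the cultures can hold other cortical cells.

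The authors deposited 1 table of whole-number read counts per Ensembl gene for each library, with no normalization and no summary lines. Trimmomatic 0.38, STAR 2.7.1a, HTSeq 0.11.2 and the mm10 build are named per the submitters' processing notes, without the role or settings of each tool. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. They affect near-identical paralogs, for which reads can be dropped or split, and overlapping or antisense genes, for which reads of both strands can be added together.

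The tables listed 48526 genes, of which 18971 had no count in any library. Symbols, coordinates (GRCm38, the assembly that mm10 names), exon lengths and GC content came from GENCODE release M21. It matched 48144 genes, and the 382 others held 0.017% of the counts. Library totals ran from 86078636 to 106974842 counts. At that depth the precision of abundant genes is set by the spread between cultures and that of genes below about 1 CPM also by counting.

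Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at its default settings, which kept 17571, and libraries were scaled with TMM factors. A quasi-likelihood model with genotype as its term was fitted, and p-values were adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of the quasi-likelihood F statistic. CPM values use the TMM-scaled library sizes and are given as mean ± SD over 3 libraries.

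Gene lists, 30 in all with 667 symbols, were written before the data were examined, and so were the tests, the alternatives and the naming rule. One of them, the sex-linked genes, served only as a check of the samples. Each other list with at least 3 tested members was tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation, camera on ranks and fry stood beside it. The edgeR p-values of each list's members were also adjusted over the list alone.

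Named genes followed a rule. Setd2 came first. Then came the 12 highest and the 12 lowest log2 fold changes among genes past the threshold with a mean of at least 2 CPM, groups that did not overlap and a symbol that is not a predicted model, Rik clone or pseudogene. From each list came up to 4 members past the threshold by smallest adjusted p, or up to 2 of the most abundant where none passed. Other genes named in the text are members of small counts, the most abundant or best known member of a list, or members of families described after their values were seen.

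The tests were also run on simulated counts for the KO against WT comparison over 17571 genes, with 50 genes changed at each fold size. The edgeR test recovered 10% of genes changed 1.25-fold, 52% at 1.5-fold, 80% at 2-fold and 96% at 4-fold, and 10.53% of its calls were false. Camera called 5 of 5 raised lists and 0 of 15 unchanged lists. The simulated genes were independent, so this does not test camera where the genes of a list are correlated. A chi-square test of the counts of each pair of replicates gave a statistic of 25.0 to 85.7 per degree of freedom, so no library was a copy of another.

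Alternatives were the replicate number as a block, DESeq2's median-of-ratios factors, library totals, upper-quartile factors, no filter beyond a total count of 1, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, a test against a log2 fold change of 0.5, and leaving out each library. After the data were seen, a term for libraries with Xist above 10 CPM, leaving those libraries out, leaving out chromosomes X, Y and M, and 10000 random lists matched on mean expression in 20 bins were added. Exact permutation tests compared single values, with 0.1 as the smallest p for 3 against 3 libraries. Figures were drawn with matplotlib 3.10.9.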

Results

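Gene expression was measured by RNA sequencing in primary renal tubular epithelial cells, which were grown from digested mouse kidney cortex in a medium with EGF and hydrocortisone. Setd2 encodes the histone methyltransferase that places trimethylation on lysine 36 of histone H3. The mice carried floxed Setd2 alleles and a Cre recombinase driven by the promoter of Cdh16 (Ksp-cadherin), a gene of kidney tubule epithelium. Cultures from Cre-positive mice are called KO here, and those from littermates with the floxed alleles alone are called WT. Each group had 3 libraries. The comparison asks which transcripts differ between cultures from mice with and without Cre. Every KO culture carried Cre and no WT culture did, so an effect of Cre itself cannot be told apart from that of the Setd2 deletion. The counted reads per library numbered 86078636, 106974842 and 95844348 for WT replicates 1 to 3 and 89951455, 95065416 and 96917379 for KO replicates 1 to 3. The labels do not state that each replicate came from a different animal, so p-values describe the spread between these libraries, part of which may be technical.

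Setd2 itself (ENSMUSG00000044791, mm10 chromosome 9, 110532597 to 110618633) was at a similar level in both groups. Its TMM-scaled abundance was 184.55, 167.76 and 152.03 CPM (read counts scaled to library size) in WT replicates 1 to 3 and 163.38, 153.66 and 158.46 CPM in KO replicates 1 to 3. The means were 168 ± 16.3 CPM in WT and 158.5 ± 4.86 CPM in KO (SD, n = 3 each). The log2 fold change was -0.08 ± 0.08 (SE), with an edgeR quasi-likelihood adjusted p of 0.481. An exact two-sided permutation test of the CPM gave p = 0.5, where 0.1 is the smallest value that 3 against 3 allows. Gene-level counts add up reads from every exon of Setd2, and the floxed exons are not given in the sources used here, so these counts do not check the deletion.

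Genotype and the sex of the mice partly coincided. Xist, the long noncoding RNA of the inactive X chromosome, was at 507 CPM in KO replicate 2 and 606 CPM in KO replicate 3. In the other libraries it was at 0.683, 0.348 and 0.642 CPM (WT replicates 1 to 3) and 0.386 CPM (KO replicate 1). The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty ran the other way. Ddx3y, for example, was at 66.9, 63.4 and 51.0 CPM in WT and 59.7 CPM in KO replicate 1, against 0.084 and 0.081 CPM in KO replicates 2 and 3. The labels give no sex.

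**Figure D1:**
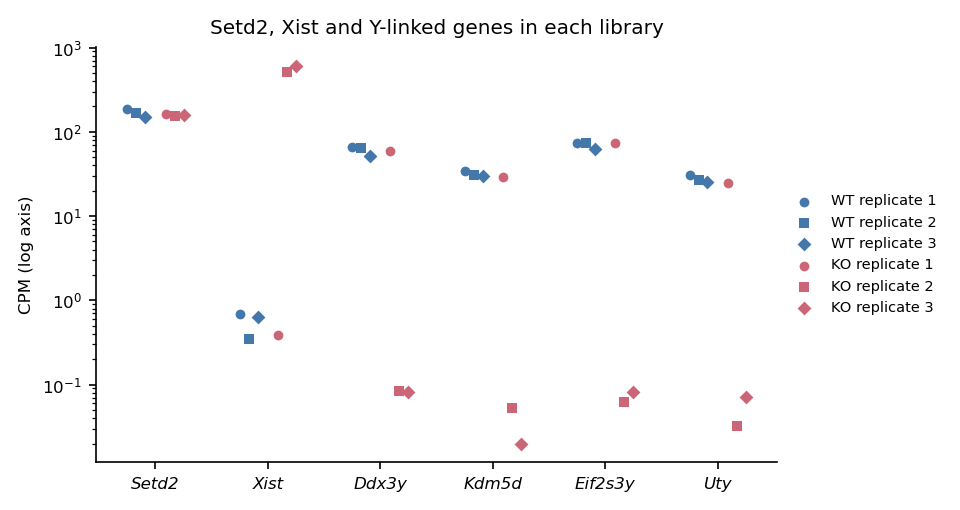
CPM (log axis) of Setd2, Xist and 4 Y-linked genes in each library, WT in blue and KO in red, with a marker shape for each replicate. Setd2 lies between 152.03 and 184.55 CPM in every library, and KO replicates 2 and 3 stand apart from the other 4 libraries in Xist and the Y-linked genes.

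Across the transcriptome, 3698 of 17571 tested genes differed between KO and WT. Of these, 2102 were higher in KO and 1596 were lower. Large changes were mostly increases: among the called genes, 706 were higher and 113 lower by a log2 fold change of at least 1. The first principal component of log2 CPM held 55.8% of the variance and placed the 3 KO libraries on the other side from the 3 WT libraries. All 3 KO values lay on one side of all 3 WT values in 7358 tested genes, 41.88% of them. Chance gives 10% on average over all splits of the libraries. Genes move together, so a single split can lie far from that average, and the share was not computed for other splits. The counts of calls are those of edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. They depended on single libraries and on a term for the Xist-positive ones. Without KO replicate 1 there were 1683 calls (1228 higher, 455 lower) and without KO replicate 3 there were 1933 (1321 higher, 612 lower), while genes lower in KO numbered 1003 without WT replicate 2 and 1044 without KO replicate 2. With a term for the Xist-positive libraries, chosen after seeing the data, 1163 genes were called (878 higher, 285 lower), and 1108 of these were among the 3698. The fold changes of the 3698 genes did not shrink in that fit (slope 1.02), but KO replicate 1 had a part in selecting them. That fit compares KO replicate 1 with WT, apart from the Xist-positive libraries, and has fewer residual degrees of freedom. Without those libraries 907 genes were called, with the spread of the remaining KO library taken from the WT group.

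**Figure D2:**
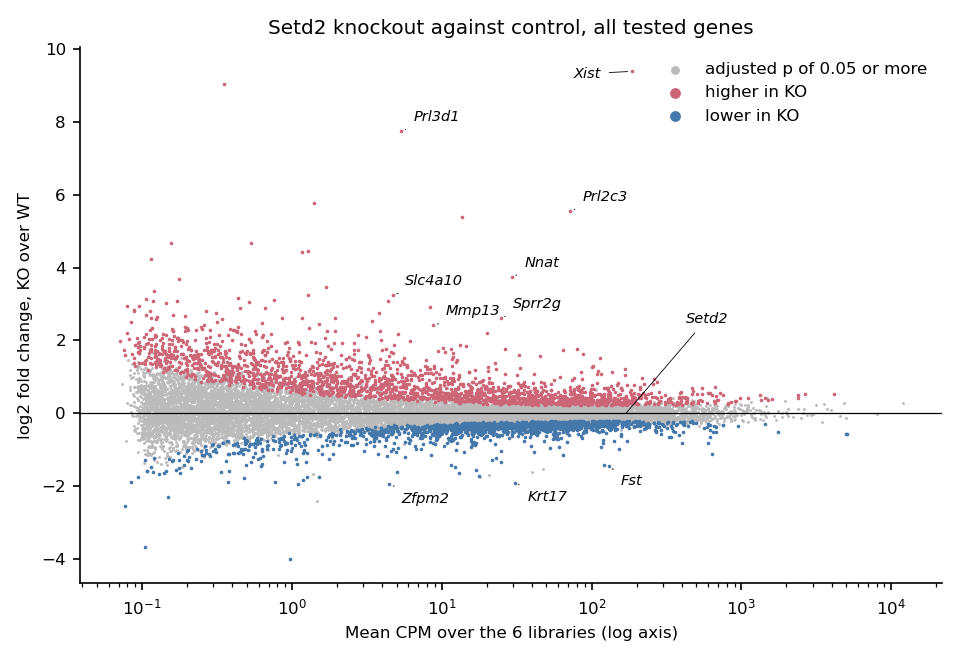
Log2 fold change of KO over WT against the mean CPM of the 6 libraries (log axis) for each of the 17571 tested genes, with genes past the threshold in red (higher in KO) or blue (lower in KO). The changes with a log2 fold change of at least 1 lie mostly above 0 (706 against 113), and Setd2 lies close to 0.

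The 12 highest increases included 3 prolactin family genes, 2 solute carrier genes and 2 Sprr genes. Prl3d1 (placental lactogen; ENSMUSG00000057170, chromosome 13, 27094190 to 27100258) rose from 0.048 ± 0.017 to 10.7 ± 8.86 CPM, a log2 fold change of 7.75 ± 0.70 (SE) with adjusted p = 5.5e-05. Its WT level rests on 14 reads in the 3 libraries together. The proliferin genes Prl2c3 and Prl2c2, also on chromosome 13, rose from 3.02 to 141 CPM and from 0.644 to 26.8 CPM, with KO replicate 1 above the other KO libraries in all 3 Prl genes. Without KO replicate 1 the log2 fold changes were 6.83 for Prl3d1, 4.79 for Prl2c3 (5.55 with it) and 4.56 for Prl2c2 (5.39 with it). Prl2c copies share long identical stretches, so how reads divide between them is uncertain. Nnat (neuronatin, an imprinted gene; ENSMUSG00000067786, chromosome 2, 157560078 to 157562522) rose from 4.12 ± 0.222 to 54.9 ± 4.96 CPM (log2 fold change 3.73 ± 0.10, adjusted p = 4.93e-09). Slc4a10, a sodium-dependent bicarbonate transporter (chromosome 2, 62046462 to 62326730), rose 9.45-fold, and Slc5a5, the sodium-iodide symporter (chromosome 8, 70882889 to 70892757), rose 8.53-fold. Sprr2f and Sprr2g, small proline-rich proteins of the cornified envelope, had log2 fold changes of 2.91 ± 0.16 and 2.61 ± 0.18. They have near-identical neighbours on chromosome 3, and Sprr2g is annotated as a polymorphic pseudogene, so their separate values are uncertain. The interferon-activated gene Ifi205 (6.79-fold), Fam163a (5.78-fold), the collagenase Mmp13 (5.32-fold) and the milk protein gene Csn3 (4.76-fold) completed the 12 highest. Adjusted p-values of the 12 genes from edgeR's quasi-likelihood test ranged from 4.93e-09 to 0.00033, and all 3 KO libraries lay above all 3 WT libraries for each.

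The 12 lowest log2 fold changes were smaller in size, from -1.95 to -1.28. Zfpm2, a cofactor of GATA transcription factors (ENSMUSG00000022306, chromosome 15, 40655035 to 41104592), fell from 7.11 ± 0.565 to 1.83 ± 0.404 CPM, a log2 fold change of -1.95 ± 0.16. The keratin gene Krt17 fell from 48.5 ± 16.6 to 12.9 ± 3.24 CPM (log2 fold change -1.91 ± 0.24). Eya4, a transcriptional coactivator (chromosome 10, 23102963 to 23350786), had a log2 fold change of -1.71 ± 0.10, and the tolloid-like protease gene Tll1 one of -1.65 ± 0.11. Among secreted and matrix-associated proteins, Fst (follistatin, an activin antagonist) fell from 191 ± 24.2 to 69.1 ± 18.9 CPM, Adamts5 (an aggrecanase) from 177 ± 4.21 to 65.4 ± 10.1 CPM, and Ltbp2 (a latent TGF-beta binding protein) from 25.2 ± 4.19 to 8.54 ± 0.717 CPM. The neutrophil chemokine gene Cxcl5, Clca3b, the cell surface proteins Flrt3 and Cntn2, and Mcam (CD146) made up the 12 lowest, with log2 fold changes from -1.61 (Cxcl5) to -1.28 (Mcam). Adjusted p-values of these 12 from the edgeR test ranged from 3.29e-06 to 0.000463.

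**Figure D3:**
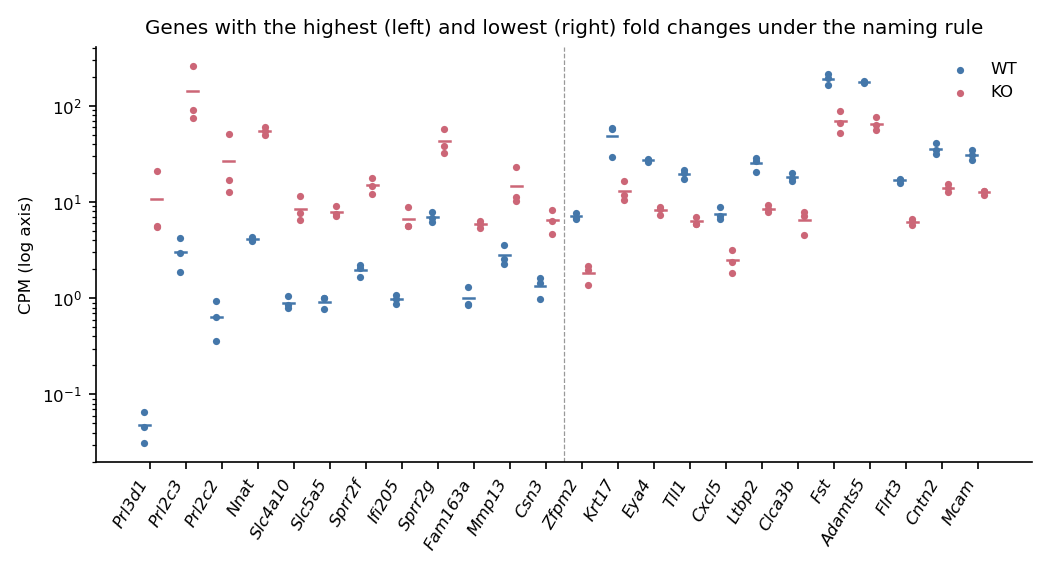
CPM (log axis) of the 12 genes with the highest and the 12 with the lowest log2 fold change under the naming rule; points are libraries (3 per group) and short lines are group means, WT in blue and KO in red. The 3 KO points lie on one side of the 3 WT points for each gene, and Prl3d1 rises from 0.048 to 10.7 CPM.

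Interferon-stimulated genes rose as a group. Of 30 measured members, 23 were higher in KO, 1 was lower and 6 did not pass the test, and adjusted over the list alone 25 were higher and 1 lower. Oasl1 rose 3.27-fold to 14.4 ± 1.91 CPM (log2 fold change 1.71 ± 0.12, adjusted p = 1.24e-05). Ifit1 and Xaf1 had log2 fold changes of 1.94 ± 0.17 and 1.74 ± 0.19, and Rtp4 rose 4.01-fold. Ifit2 was the member that fell, by 0.64 on the log2 scale. The list's mean log2 fold change was 1.09, and limma's camera test with a preset inter-gene correlation of 0.01 gave an adjusted p of 2.26e-12 over 28 lists. The adjusted p was 0.256 with an estimated correlation. Antigen presentation genes moved with them, with 9 of 17 measured members higher and none lower, and 12 higher adjusted over the list alone. This list holds class I genes, the class II genes H2-Ab1 and H2-Eb1, which were not called, and Cd274, which was higher. It also holds Tap1, Tap2, Tapbp, Psmb8, Psmb9 and Psmb10, none of which was called (edgeR adjusted p from 0.104 to 0.644). H2-K1, a class I heavy chain, rose from 226 ± 25.7 to 338 ± 11.53 CPM. H2-T23 rose 1.85-fold, and Nlrc5, the transactivator of class I genes, had a log2 fold change of 1.83 ± 0.27 at a low level, from 0.316 to 1.13 CPM. This list had a camera adjusted p of 3e-06, and adjusted p = 0.442 with an estimated correlation. Class I genes are near-identical paralogs, so reads may be split between them. Leukocyte marker genes rose in the same libraries, with a summed level of 35.99 ± 2.92 CPM in WT and 53.95 ± 5.28 CPM in KO.

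**Figure D4:**
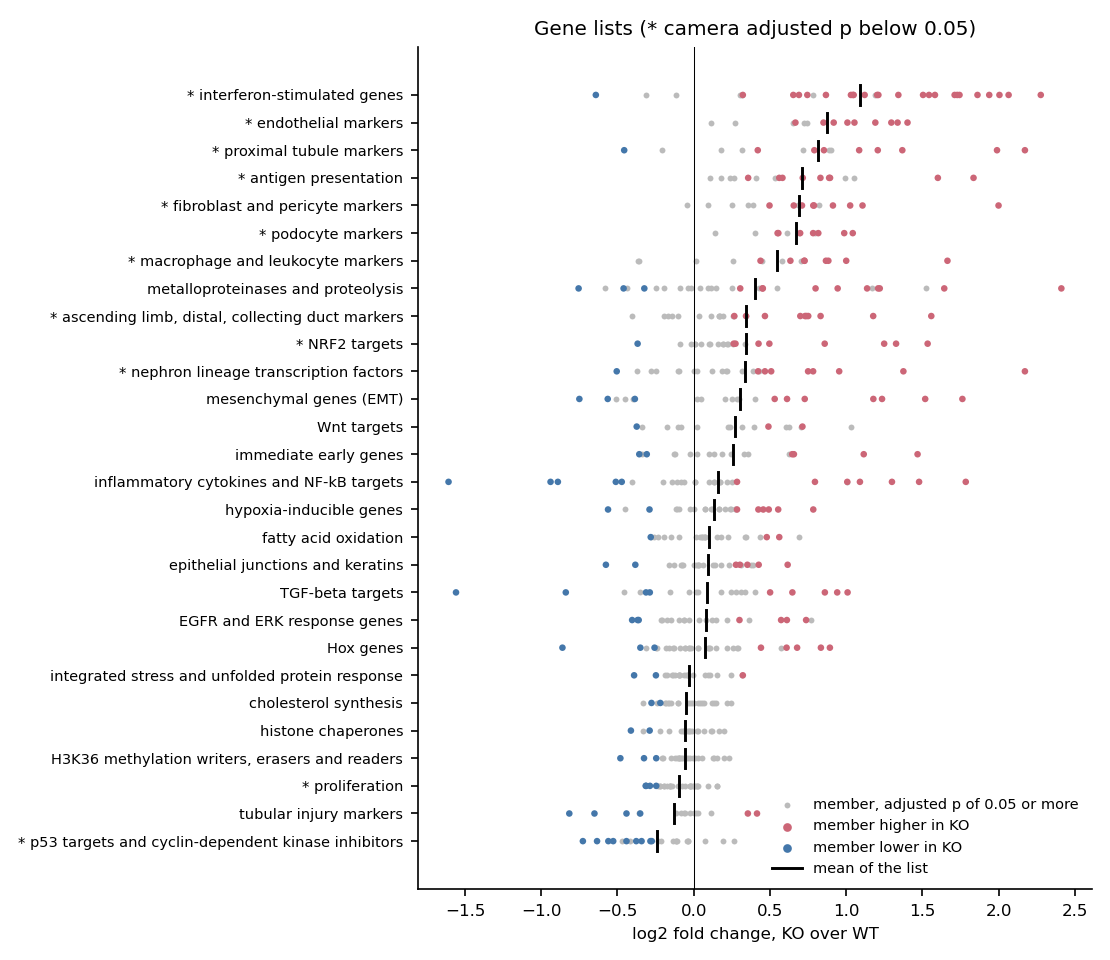
Log2 fold change of KO over WT for the tested members of each of 28 gene lists; each point is a gene (grey where the adjusted p is 0.05 or more, red higher, blue lower), black bars are list means and asterisks mark camera adjusted p below 0.05. The interferon list has the highest mean, 1.09, and the list of p53 targets the lowest, -0.24.

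Markers of cells other than tubular epithelium were also higher in KO. Endothelial markers rose in 9 of 14 measured members (11 adjusted over the list alone) with none lower, among them the receptor gene Kdr, from 1.59 ± 0.415 to 4.20 ± 1.23 CPM, and Pecam1, with a log2 fold change of 1.05 ± 0.20. Fibroblast and pericyte markers rose in 9 of 16 members (11 adjusted over the list alone) with none lower, including the receptor gene Pdgfrb, from 3.15 ± 0.447 to 5.92 ± 1.09 CPM. Podocyte markers rose in 7 of 12 members (9 adjusted over the list alone) with none lower, including Podxl, from 79.0 ± 1.51 to 139 ± 13.1 CPM, and Cdkn1c, from 8.56 ± 0.411 to 17.7 ± 1.17 CPM. Macrophage and leukocyte markers rose in 8 of 15 members (9 adjusted over the list alone) with none lower, including Lyz2, from 16.04 ± 1.87 to 24.9 ± 3.21 CPM. Camera adjusted p-values were 2.76e-05 for the endothelial, 0.000136 for the fibroblast, 0.000136 for the podocyte and 0.00214 for the leukocyte list. With an estimated correlation the adjusted p-values were 0.442, 0.449, 0.442 and 0.449 in the same order, and fry gave 0.0568 for the leukocyte list. The erythroid list had only Alas2 above the filter, at 0.199 CPM in WT and 0.128 CPM in KO, and was not tested as a list.

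Summed over each list, the markers stood 1.72 times as high in KO as in WT for podocytes, 1.68 times for endothelium, 1.499 times for leukocytes and 1.33 times for fibroblasts and pericytes. An exact permutation test of the sums gave p = 0.1, the smallest possible with 3 libraries per group, for the podocyte, endothelial and leukocyte lists and p = 0.3 for the fibroblast list. The endothelial sum was low, 26.1 ± 0.96 CPM in WT and 43.6 ± 7.42 CPM in KO. Some sums rest largely on a single gene. Podxl held 79.0 of the 118.42 CPM of the podocyte sum in WT and 139 of 203.89 CPM in KO. Acta2, which was not called, held 52.8 of the 102.8 CPM of the fibroblast sum in WT and 56.3 of 136.29 CPM in KO.

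**Figure D5:**
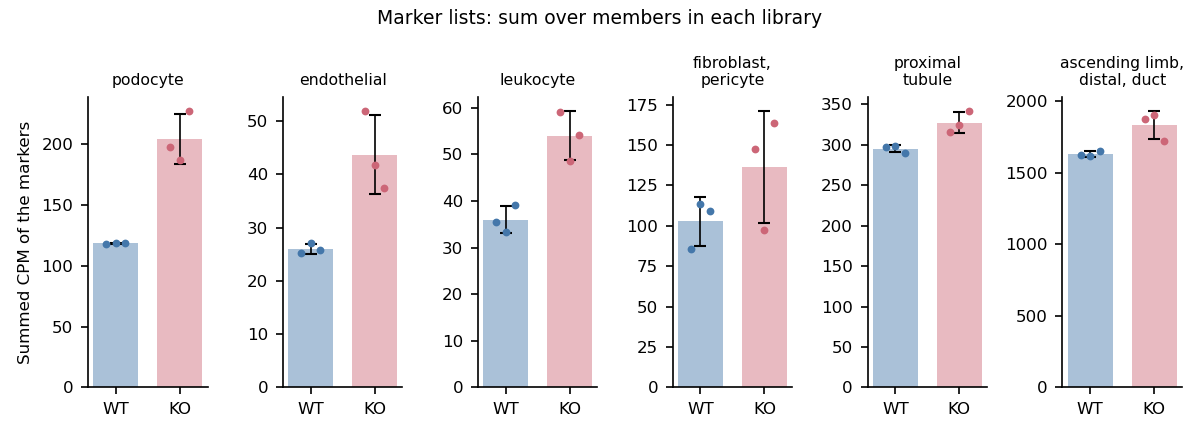
Summed CPM of the markers of 6 cell types in each library, as points, with the mean of 3 libraries (bar) and its SD (error bar), WT in blue and KO in red; each panel has its own axis, starting at 0. The KO points lie above the WT points in every panel except that of fibroblasts and pericytes, where KO replicate 2, at 97.4 CPM, lies within the WT range.

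Markers of tubule segments rose as well. Among proximal tubule markers, 8 of 15 measured members were higher and 1 lower (9 and 1 adjusted over the list alone). Gatm, which makes the creatine precursor guanidinoacetate, rose from 5.08 ± 0.27 to 11.7 ± 0.272 CPM. The aminopeptidase gene Anpep had a log2 fold change of 1.37 ± 0.25 at a low level, from 0.448 to 1.16 CPM. Slc4a4, the basolateral bicarbonate cotransporter, fell by 0.46 on the log2 scale, a call that was lost with the Xist term (adjusted p = 0.0772). Among markers of the thick ascending limb, distal tubule and collecting duct, 10 of 24 rose and none fell (11 higher adjusted over the list alone). Hsd11b2, which inactivates glucocorticoids in mineralocorticoid target cells, rose from 10.2 ± 1.98 to 23.02 ± 1.73 CPM. The water channel gene Aqp3 had a log2 fold change of 1.56 ± 0.33 at a low level, from 0.172 to 0.512 CPM. Cdh16, the source of the Cre promoter and the most abundant marker of this list, went from 735 ± 22.4 to 884 ± 60.2 CPM (adjusted p = 0.0366). Camera gave adjusted p-values of 0.00237 for the proximal and 0.00623 for the distal list, and with an estimated correlation they were 0.442 and 0.256. With genes of a mean CPM of at least 1, the proximal list had an adjusted p of 0.0783. The summed markers, which abundant members such as Ass1 and Cdh16 dominate, were 1.11 and 1.12 times as high in KO as in WT. The median log2 fold changes over members were 0.85 (proximal) and 0.26 (distal), beside 0.69 for podocyte, 0.89 for endothelial, 0.63 for leukocyte and 0.70 for fibroblast and pericyte markers.

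Nephron lineage transcription factors leaned the same way, with 8 of 23 members higher and 1 lower (9 and 2 adjusted over the list alone). Tfap2a rose from 20.8 to 35.03 CPM and Irx3 from 3.91 to 7.59 CPM. Irx2 fell by 0.50 on the log2 scale, a call that was lost with the Xist term (adjusted p = 0.108). The camera adjusted p of 0.0433 lay close to the threshold, and it was 0.612 with an estimated correlation, 0.155 with the Xist term, 0.0876 without WT replicate 1, 0.0878 without WT replicate 3 and 0.11 without KO replicate 3. Of the list's genes, 6 also belong to other lists used here.

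The list of p53 targets and cyclin-dependent kinase inhibitors was lower in KO on balance. Of 23 measured members, 9 were lower and none higher, and adjusted over the list alone 10 were lower and 2 higher. Eda2r, a TNF receptor family member, fell from 26.3 ± 1.85 to 15.9 ± 1.77 CPM and the kinase inhibitor gene Cdkn2c from 8.83 ± 0.132 to 5.69 ± 0.455 CPM. Plk2 fell from 761 ± 44.8 to 528 ± 72.7 CPM, a call that ended with the Xist term. Cdkn1a (p21) was at 281 ± 27.0 CPM in WT and 259 ± 6.8 CPM in KO, with adjusted p = 0.326. Cdkn1c, a cyclin-dependent kinase inhibitor counted with the podocyte markers and not in this list, rose from 8.565 ± 0.411 to 17.66 ± 1.17 CPM. The list's mean log2 fold change was -0.24, with a camera adjusted p of 0.00272 and adjusted p = 0.256 with an estimated correlation.

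Proliferation genes shifted little. Of 30 members, 4 were lower and none higher, also adjusted over the list alone. The 4 were Mcm6, Cdk1, Bub1 and Tyms, with log2 fold changes from -0.32 to -0.25. All 4 calls ended without KO replicate 1 (adjusted p from 0.064 to 0.119) and without KO replicate 3 (0.0853 to 0.139). The log2 fold changes of the 4 genes were then -0.317 to -0.24 and -0.25 to -0.213. Mki67 was at 722 ± 101 CPM in WT and 802 ± 54.0 CPM in KO (adjusted p = 0.321). The list had a mean log2 fold change of -0.10 and a camera adjusted p of 0.0438, which was 0.755 with an estimated correlation, 0.48 with the Xist term, 0.0569 without WT replicate 1, 0.0876 without WT replicate 2 and 0.306 without KO replicate 3. The adjusted p of fry was 0.238.

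Targets of NRF2, the transcription factor of the antioxidant response, were higher in KO for 8 of 23 members and lower for 1 (10 and 1 adjusted over the list alone). The glutathione transferase gene Gsta4 rose from 19.8 ± 1.01 to 47.1 ± 5.62 CPM, and Nqo1, a quinone reductase, from 14.6 ± 1.02 to 26.5 ± 3.67 CPM. Gsta1 and Gsta2 had log2 fold changes of 1.53 ± 0.22 and 1.33 ± 0.22, and as close paralogs may share reads. Abcc4, an efflux transporter and the most abundant member, fell by 0.37 on the log2 scale. The glutamate-cysteine ligase and thioredoxin reductase genes of the list were not among the called members. The camera adjusted p was 0.003, and adjusted p = 0.628 with an estimated correlation. The fry test, which asks whether the list moves one way on balance, gave 0.0568.

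Genes of inflammation, matrix and mesenchyme changed in both directions, and none of these lists passed the camera test. Among inflammatory cytokines and NF-kB targets, 7 of 28 were higher and 5 lower (8 and 6 adjusted over the list alone; camera adjusted p = 0.566, and 0.755 with an estimated correlation). The monocyte chemokine gene Ccl2 rose from 4.62 ± 0.209 to 15.9 ± 4.396 CPM and Ccl20 from 58.7 ± 13.6 to 145 ± 22.6 CPM, while Cxcl5 was among the lowest genes above. Among mesenchymal genes of the epithelial-mesenchymal transition, 7 of 20 were higher and 3 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.315, and 0.755 with an estimated correlation). Vim (vimentin) rose from 36.2 ± 2.11 to 123 ± 30.6 CPM and Zeb2 from 4.43 to 10.0 CPM, and Fn1 (fibronectin), the most abundant member, fell from 5957 ± 97.6 to 4028 ± 315 CPM. Summed endothelial, leukocyte and fibroblast markers were also higher in KO, at 1.675, 1.499 and 1.326 times WT (exact permutation p = 0.3 for fibroblasts). Which cells carried the rises of Vim and Zeb2 was not tested. Among matrix metalloproteinases and pericellular proteolysis genes, 10 of 29 were higher and 3 lower (14 and 5 adjusted over the list alone; camera adjusted p = 0.0861, and 0.612 with an estimated correlation). Adam8 rose from 101 ± 2.89 to 236 ± 27.5 CPM and Mmp13 was among the highest genes above. The 3 lower members, named after their values were seen, were Mmp11, Adamts1 and Timp2. Among TGF-beta targets, 5 of 21 were higher and 4 lower (8 and 4 adjusted over the list alone; camera adjusted p = 0.562, and 0.773 with an estimated correlation). Tgfb1 had a log2 fold change of 0.86 ± 0.11 and Tgfb2 one of -0.84 ± 0.13.

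The remaining lists had camera adjusted p-values from 0.0861 to 0.93. In the H3K36 methylation list, which holds writers, erasers and readers of the mark, 3 of 27 members were lower and none higher (1 lower adjusted over the list alone). They were the demethylase gene Riox1, the methyltransferase gene Nsd2 and the reader gene Mtf2, with log2 fold changes of -0.48 ± 0.11, -0.25 ± 0.08 and -0.33 ± 0.10. Without KO replicate 1 their log2 fold changes were -0.421, -0.22 and -0.289, with edgeR adjusted p-values of 0.0674, 0.163 and 0.148. Calls for histone chaperones were limited to 2 lower of 20, for cholesterol synthesis to 2 lower of 24, for fatty acid oxidation to 2 higher and 1 lower of 23, and for the integrated stress and unfolded protein response to 1 higher and 2 lower of 24. Hypoxia-inducible genes had 6 higher and 2 lower of 25, with Aldoa from 630 to 886 CPM and Hk1 from 360 to 483 CPM. Immediate early genes had 4 higher and 2 lower of 18, EGFR and ERK response genes 4 and 3 of 22, Wnt targets 2 and 1 of 16, and Hox genes 5 and 3 of 32. Tubular injury markers had 2 higher and 4 lower of 16, and Prom1, a marker of scattered tubular cells, fell from 516 ± 25.9 to 293 ± 11.4 CPM. Among epithelial junction genes and keratins, 5 of 25 were higher and 2 lower. Adjusted over each list alone, the counts were 2 lower for histone chaperones, none for cholesterol synthesis or the stress response, and 1 higher for fatty acid oxidation. They were 8 higher and 2 lower for hypoxia, 5 and 3 for immediate early genes, 7 and 5 for EGFR and ERK response genes, 5 and 2 for Wnt targets, 5 and 3 for Hox genes, 2 and 5 for injury markers, and 6 and 2 for epithelial junctions.

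Camera adjusted p-values of these lists were 0.301 for H3K36 methylation, 0.385 for histone chaperones, 0.385 for cholesterol synthesis, 0.473 for fatty acid oxidation, 0.484 for the stress response and 0.0861 for hypoxia. They were 0.301 for immediate early genes, 0.93 for EGFR and ERK response genes, 0.3 for Wnt targets, 0.81 for Hox genes, 0.315 for injury markers and 0.331 for epithelial junctions. With an estimated correlation the adjusted p-values ran from 0.639 for injury markers to 0.94 for Hox genes.

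The set tests leave a limit that applies to each list above. Camera with the preset correlation called 12 of 28 lists, 10 upward and 2 downward, and with an estimated correlation it called none. With the Xist term 10 of the 12 stayed past the threshold.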

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

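The settings that use Xist or leave out chromosomes and the expression-matched lists were chosen after seeing the data; the others were fixed before. Replacing TMM by other factors, changing the filter or using DESeq2 or limma-voom gave 2898 to 4726 changed genes, against 3698. Leaving out 1 library gave 1683 to 3766 changed genes, 1228 to 2142 higher and 455 to 1624 lower, with the lowest values without KO replicate 1. It gave 10 to 14 gene lists past the threshold. A term for the Xist-positive libraries gave 1163 changed genes (878 higher, 285 lower), and leaving those libraries out gave 907 (728 higher, 179 lower); both rest on KO replicate 1 against WT, with fewer samples or residual degrees of freedom. A test against a log2 fold change of 0.5 called 486 genes (425 higher, 61 lower), and 819 had an absolute log2 fold change of at least 1, both stricter by construction. With an estimated correlation 0 lists passed (unadjusted p was below 0.05 for the interferon, p53 and distal tubule lists, at 0.0268, 0.0206 and 0.0275), where fry called 10 and ranks 12; the cause was not tested. Setd2 stayed below WT and short of the threshold in 17 settings (log2 fold change -0.155 to -0.001, adjusted p 0.162 to 0.99). Leaving out 1 library, the KO over WT ratio of summed markers was 1.625 to 1.793 for podocytes, 1.518 to 1.795 for endothelium, 1.428 to 1.574 for leukocytes, 1.192 to 1.515 for fibroblasts, 1.085 to 1.128 for proximal and 1.103 to 1.158 for distal tubule, and 0.524 to 0.692 for erythroid markers. The 12 highest and 12 lowest genes kept their calls in each of 17 settings, which leave out the test against 0.5. They were picked for extreme fold changes, which favours this. These genes by rule, and nearly all those named from lists, had groups that did not overlap, which makes a reversal unlikely. Of 101 called genes named from lists, 52 lost the call in some setting: 29 with a library left out, 51 in the Xist settings and 10 in others, and none reversed. The replicate numbers did not pair the libraries. Deviations from the group means correlated at 0.042, -0.146 and 0.032 for libraries with the same number. With the replicate block 3594 genes were changed (2139 higher, 1455 lower), and the nephron transcription factor and proliferation lists had adjusted p = 0.0618. Lists that were not called reversed in camera's direction, which can differ from the sign of the mean. The EGFR and ERK list had a mean log2 fold change of 0.082 with the replicate block, 0.065 with no filter, 0.064 without WT replicate 3 and 0.06 without KO replicate 3 (0.06 to 0.11 with a library left out). The Hox list had -0.095 with the Xist term, -0.096 without those libraries, 0.065 without WT replicate 1 and -0.04 without KO replicate 3 (-0.04 to 0.166 with a library left out). The nephron call ended with upper-quartile factors (adjusted p = 0.0504), no filter (0.0631) and a mean CPM of at least 1 (0.0828), and the proliferation call with upper-quartile factors (0.0594), a mean CPM of at least 1 (0.121) and fry (0.238). The mesenchymal list passed without KO replicate 2 (0.0448). Among expression-matched random lists, the 12 called lists stood at percentile 98.99 or above, or at 2.09 or below for the 2 lower ones, and of the lists not called the metalloproteinase (99.78), mesenchymal (98.04) and injury (1.94) lists stood near these bounds or beyond, with the immediate early (97.11) and junction (96.09) lists next. The metalloproteinase list passed in 4 tested settings (adjusted p 0.0264 to 0.171 over all but the estimated correlation) and the hypoxia list in 3 (0.0276 to 0.305).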

Other observations

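Other gene families, picked after their values were seen, also held called genes and were not tested as sets. Of 12 tested prolactin family genes, all on chromosome 13, 10 were higher in KO, Prl6a1 was lower and Prl2c1 was not called. Prl8a9 rose from 0.05 ± 0.027 CPM in WT to 5.43, 1.56 and 1.31 CPM in KO replicates 1 to 3, and Prl3d2 from 0.101 ± 0.044 CPM to 4.57, 1.16 and 1.04 CPM, so KO replicate 1 carries much of both means. Of 7 tested Sprr genes, which encode cornified envelope proteins, 6 were higher, and Sprr1a rose from 29.7 to 98.9 CPM (log2 fold change 1.74 ± 0.19, edgeR adjusted p = 0.00019). Of 16 tested mitochondrially encoded genes, 7 were higher and none lower, among them mt-Nd1, from 3408 ± 412 to 4940 ± 778 CPM. The mitochondrial share of counts was 2.674%, 2.647% and 2.154% in WT and 3.509%, 2.758% and 3.408% in KO (exact two-sided permutation p = 0.1, the smallest possible).

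In what follows, the tests of the sex of the mice, of GC content and exon length, of other cell types and of shared Prl reads were chosen only after the results they bear on were seen. With 10 splits of the 6 libraries into 3 and 3, no share below 0.05 can be reached. The real split gave 3698 changed genes (2102 higher and 1596 lower) and the highest of the other splits 0, so it was 1 of the 10 with a count as large. For gene lists the real split gave 12 and the highest other split 13, so 2 of the 10 gave as many. Each other split keeps 2 libraries of one genotype on a side and so holds part of the genotype difference, which keeps its list calls from being a count free of genotype. Such a split also puts genotype into the spread within each side, which lowers gene calls. The 0 was therefore likely from the design and says little about chance. The interferon, antigen presentation, p53 and distal tubule lists had a smaller p in the real split than in any other, and the endothelial, fibroblast, podocyte, leukocyte, proximal, NRF2, nephron and proliferation lists did not. The smallest camera p of another split was 3.29e-09 for the fibroblast list, against 2.1e-05 in the real split. For the interferon list it was 2.8e-06 against 8.09e-14. Whether genotype lies behind the small values of other splits was not tested.

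The sex of the mice was weighed as a source of the calls, since only KO libraries carried Xist. With a term for the Xist-positive libraries, 1123 genes outside chromosomes X and Y stayed past the threshold, and the term itself called 10 genes, of which 4 lay outside X and Y (Prl3d1, Prl3d2, Prl8a9 and Xirp2). In that fit the genotype effect rests on KO replicate 1, the only KO library without Xist, and the slope of 1.02 over the 3698 genes includes that library's part in selecting them. Genes outside X and Y were therefore called from the Xist-positive KO libraries and 2 WT libraries, and KO replicate 1 was set against the WT library left out. Differences were taken of log2 CPM with a small constant added, which shrinks them for low genes. Over the 3 choices of that library, 96.2% to 99.5% of 884 to 2212 genes moved the same way. Slopes of these differences on the edgeR fold changes were 0.531 to 0.545, against 0.494 to 0.517 for the Xist-positive libraries measured alike. The constant can lower both, so neither can be set against the slope of 1.02. KO replicate 1 differed from WT replicates 1, 2 and 3 by median log2 values of 0.537, 0.672 and 0.56 in the selected direction. The median absolute log2 fold changes in the fits that selected the genes were larger, at 0.591, 0.972 and 0.744. They are edgeR values on another scale, so the gap does not measure a loss of effect. The shared direction and the slopes speak against sex as the main source, but 1 KO library carries them, so sex stays open.

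Most changes with a log2 fold change of at least 1 were increases, 86.2% of 819 (95% exact binomial interval 83.6 to 88.5, for counting over genes, which are not independent). Over 4 equal bins of the tested genes the share was lowest at 80.3% (interval 74.4 to 85.3) by GC content and 79% (73.2 to 84) by exon length. This argues against either as the whole source of these increases, although the share rose with both, to 91.2% and 92.2%. Over all tested genes the median log2 fold change also rose with GC content, from -0.101 through -0.052 and 0.016 to 0.116. How far the smaller calls follow GC content was not tested. Among genes under 1 CPM, some lay within 10 kb downstream of a same-strand gene of at least 10 CPM. Their median log2 fold change was 0.03 above that of genes beside one on the other strand (permutation p = 0.64). It was below that of genes with no such neighbour (-0.118, permutation p = 0.0084). The strand setting is not given, so read-through from the other strand could raise the compared genes too. Genes without a neighbour may differ in other ways, so these values do not decide on read-through. Low counts may contribute: among genes with a mean of at least 10 CPM the share was 73.4% (interval 60.9 to 83.7, 47 against 17 genes), and the median log2 fold change was 0.13 below 0.5 CPM and -0.06 from 10 to 50 CPM. Other cell types in the cultures stay open too: the lowest median log2 fold change among the podocyte, endothelial, leukocyte and fibroblast lists was 0.634, but the tubule lists also rose (medians 0.854 and 0.262), and no biological explanation was tested.

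Among genes that met the naming rule, 3 prolactin family genes had the highest log2 fold changes, with Prl2c3 at 260, 90.2 and 74.2 CPM in the KO libraries and 4.25, 2.94 and 1.88 CPM in WT. Reads shared with the near-identical Prl2c copies could raise several of them at once, but 7 higher Prl genes share no 50-base stretch with a Prl2c gene. Of these, Prl3d1, Prl3d2 and Prl3d3 share such stretches with other Prl genes, so reads can couple them too, and the 4 others (Prl8a9, Prl7b1, Prl2a1 and Prl5a1, with 757, 276, 60 and 84 reads in the KO libraries together) share none with any of 25 annotated Prl genes. A wider placental program was predicted to lift other placental genes: a list of 55 without Prl genes had 19 tested members, 6 higher and 2 lower, and its mean stood at percentile 84.55 of 10000 expression-matched random lists, short of the 95th. The higher genes lay in 2 regions of chromosome 13, with Prl2c3, Prl2c2 and Prl2c5 from 12790816 to 13191923 and the rest from 27094190 to 28151611, where Prl6a1 fell.

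The rise of Nnat and Cdkn1c, both imprinted, led to the hypothesis that imprinted genes lean higher in KO. A list of 50 imprinted genes without Nnat, Cdkn1c and Ndn had 39 tested members, of which 5 were higher and 2 lower. Its mean log2 fold change of 0.16 stood at percentile 91.21 of the matched random lists, short of the 95th set in advance, and so gave no support for the hypothesis.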
